A study of Arabidopsis thaliana with 6 samples.

How the data were processed

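RNA was taken from portions of style tissue holding grown pollen tubes, from 3 wild-type and 3 paps1-1 samples of Arabidopsis thaliana. Per the labels' protocols, it was isolated with the PicoPure kit with DNase treatment on the column, mRNA libraries were prepared by a service provider and sequencing was on an Illumina HiSeq2000. Per the submitters' processing notes, STAR was used with the TAIR10 genome; the version of STAR, the annotation and the alignment settings are not given in the sources used here. The values used are the deposited counts, whole reads per gene in the layout of STAR's gene count table, with one table per library and no normalization by the authors that the values show. Each table gives counts with strand ignored and counts for either strand. The totals of both strands differed by a ratio of 1.02 to 1.07, so the libraries do not mark strand and the unstranded counts were used.

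Groups were taken from the labels. The labels call only the wild-type samples biological replicates, and nothing in them says that the paps1-1 samples came from separate plants, so p-values measure the spread between these samples, which for paps1-1 may be technical. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom between libraries over genes was at least 31.2. Counts naming no gene stayed out of library sizes and tests. Unmapped reads made up 3.06%, 3.56% and 4.36% of all reads in wild-type replicates 1 to 3 and 3.84%, 1.32% and 2.97% in paps1-1 replicates 1 to 3. Multi-mapping reads made up 7.28%, 11.9% and 15.1%, and 28.0%, 74.6% and 7.75%. Reads outside genes made up 2.76%, 3.53% and 3.95%, and 4.95%, 9.93% and 2.71%. Exact Clopper-Pearson intervals were given at 95%. Genes of the chloroplast and mitochondria were not analysed here, so the share of organelle transcripts, for which a test had been set, was not used here.

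Gene names, products, kinds of gene and locus order came from the annotation of assembly TAIR10.1, which matched 32835 of 33323 gene identifiers; 488 did not match. As the build differs in name from that of the counts, no coordinates were taken from it.

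Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10, which left 18317. Library sizes were scaled by TMM factors, and CPM values use these. Genotypes were compared with the quasi-likelihood test of edgeR (glmQLFit and glmQLFTest, two-sided, R 4.3.3), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.263. Fold changes are log2 of paps1-1 over wild type. Where all libraries of a genotype had no read, a lower bound was computed against 3 reads over the group, and with 1 to 10 reads a ratio with an exact counting interval. The test was tried on simulated data with 200 of 18006 genes changed in a paps1-1 against wild type design: 22% of 2-fold and 97% of 4-fold changes were recovered, with 3 false calls among 122. The changed genes were drawn from those with mean log2 CPM of at least 2, and genes varied independently. Recovery at lower counts, or with an outlying library, was not measured.

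There were 17 gene lists with 365 genes in all, of which 305 were tested: 3' end processing; poly(A) binding, deadenylation and decapping; nuclear exosome and RNA surveillance; SAUR genes; auxin response; pollen and pollen tube; sperm cell; style, stigma and transmitting tract; ovule, synergid and egg cell; tapetum and anther; photosynthesis; salicylic acid and immune response; wounding and jasmonate; redox; heat shock; RNA-directed DNA methylation and silencing; and the unfolded protein response. Members were matched by symbol where the reference ties it to 1 gene and otherwise by identifier, and for 2 members, TET11 and EXL5, the symbol led to another locus than the identifier listed; for EXL5 that locus is an unrelated EXORDIUM-like gene. Lists were tested with camera on log2 CPM (limma 3.58.1, preset correlation 0.01, adjusted over 17 lists), with an estimated correlation and with fry as alternatives. Library means of each list were compared with an exact permutation test of 3 against 3 libraries, whose smallest p is 0.1.

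The groups, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text may name PAPS1 to PAPS4, the 10 genes per direction with the largest fold change and the 5 with the smallest p among called genes with mean log2 CPM of at least 2 and groups that do not overlap, and up to 4 genes per list with the smallest p. Genes of chromosomes 2, 4 and 5 named among the other observations, 8 per direction, were chosen after their values were seen.

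Alternatives were the counts of the strand with the larger total, RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, each library left out, the replicate number as a block, a covariate for the balance of pollen and style lists, and a 2-fold minimum. Chosen after seeing the data were leaving out ribosomal RNA genes, testing chromosomes 2, 4 and 5 alone, leaving out wild-type replicate 3 with paps1-1 replicate 2, testing protein-coding genes alone and matching list members by identifier.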

Results

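Transcript levels were measured by sequencing in complexes of Arabidopsis thaliana style tissue with pollen tubes grown through it, from wild-type Col-0 plants and from plants carrying paps1-1. PAPS1 encodes a nuclear poly(A) polymerase, an enzyme that adds the poly(A) tail to newly made transcripts, and paps1-1 is a mutant allele of it which the labels place in Col-0. There were 3 wild-type and 3 paps1-1 libraries. The labels do not say whether the pollen tube, the style or both carried the mutation. Reads counted in genes came to 21031017, 13707799 and 19288861 in wild-type replicates 1 to 3, and to 15092276, 4541233 and 18717968 in paps1-1 replicates 1 to 3. A count of 3 reads, the floor used here, corresponded to between 0.152 and 0.638 CPM (gene reads scaled to library size) in single libraries, and a library with no read of a gene allows a level up to that. In paps1-1 replicate 2, 74.6% of all 32598413 reads mapped to several places (95% Clopper-Pearson interval 74.57 to 74.60), and the 18S ribosomal RNA gene AT3G41768 took 10.5% of its gene reads (10.4 to 10.5). In the other 5 libraries that gene took between 0.110% and 0.732%. Intervals and floors cover counting error only.

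**Figure D1:**
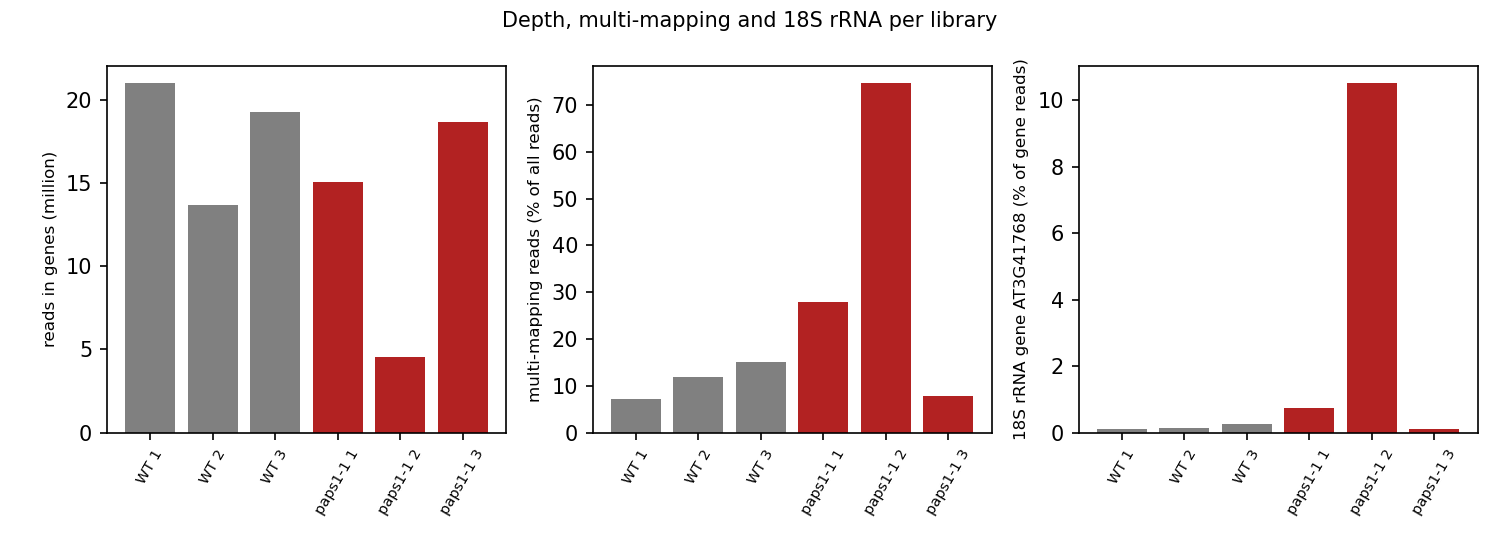
Bars give, for each of the 6 libraries (grey, wild type; red, paps1-1), the reads in genes on an axis in M reads, the multi-mapping reads as a percent of all reads, and the 18S ribosomal RNA gene AT3G41768 as a percent of gene reads. The library of paps1-1 replicate 2 had the fewest gene reads (4541233) and the highest multi-mapping share (74.6%).

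The level of the mutated gene itself was examined first. PAPS1 (AT1G17980) stood at 143, 101 and 104 CPM in the wild-type libraries and at 88.4, 99.4 and 59.9 CPM in the paps1-1 libraries. Its log2 fold change of -0.49 (SE 0.28, n = 3 per genotype) did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.609). Its paralogs did not pass either: PAPS2, at 83.2 ± 43.6 CPM in wild type (SD, n = 3), had a log2 fold change of -0.33, PAPS3 one of -0.47 and PAPS4 one of -0.60. PAPS4 was the most abundant of these polymerase transcripts, at 367 ± 183 CPM in wild type and 242 ± 86.8 CPM in paps1-1 (SD, n = 3). The transcript level of an allele need not differ from wild type, so PAPS1 was not a check of the labels here.

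The comparison of paps1-1 with wild type asked which transcripts differ in the complexes. The transcripts with the largest losses included AT1G34095, an uncharacterised protein-coding gene, which stood at 1929 ± 659 CPM in wild type and at 4.33 ± 1.97 CPM in paps1-1 (SD, n = 3; log2 fold change -8.85, SE 0.56). The neighbouring GDSL-type lipase genes AT3G43550 and AT3G43570 fell from 438 ± 108 to 1.01 ± 0.323 CPM and from 196 ± 36.5 to 0.853 ± 0.403 CPM. The thionin-family gene AT1G34792 had no read in any paps1-1 library and was at least 213-fold lower there, with the floor of 3 reads taken over the group. Among the gains, the protein-coding gene AT1G41820 rose from 0.891 ± 0.496 to 268 ± 164 CPM, and AT1G11160, a WD40-repeat protein gene, rose from 0.709 ± 0.323 to 30.8 ± 3.61 CPM. All of these lay on chromosome 1 or 3.

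Of 18317 genes tested, 429 differed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 213 higher and 216 lower in paps1-1. In 423 of them the 3 values of one genotype all lay above the 3 of the other; over all tested genes this held for 2699, or 14.7%, where chance gives 10%. Changes of at least 16-fold were found for 123 of the 429, and 179 changed less than 4-fold. No read was counted in any wild-type library for 35 of the called genes, and none in any paps1-1 library for 11. Further genes with large losses had 5 or 6 reads over the paps1-1 libraries, so the depth-corrected ratio of wild type to paps1-1 is given with its counting interval. It was 869 (372 to 2680) for AT1G31990, 751 (322 to 2310) for AT3G28153 and 237 (108 to 646) for AT3G32920, which encodes a P-loop nucleoside triphosphate hydrolase family protein. AT3G60565 and AT1G22010 had no read in paps1-1 and were at least 379-fold and at least 119-fold lower. AT3G43526 had 575 reads over the wild-type libraries and 1 over the paps1-1 libraries, a ratio of 475 (85.0 to 18800). The pseudogene AT3G60930 fell by 6.06 on the log2 scale (SE 0.35). AT3G28153, AT3G43526 and AT3G60565 are annotated as pseudogenes too.

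Most of the genes with the largest gains were annotated as pseudogenes. AT3G30836 and AT3G30837 rose to 45.0 ± 7.37 and 37.0 ± 5.07 CPM in paps1-1 (SD, n = 3). Each had 4 reads over the wild-type libraries, and the depth-corrected ratio of paps1-1 to wild type was 561 (counting interval 219 to 2060) and 456 (178 to 1680). AT3G43675 and AT3G44215, also with 4 reads in wild type, had ratios of 311 (121 to 1150) and 194 (75.3 to 714), and AT3G44325 rose by 6.51 on the log2 scale (SE 0.42). For genes with 1 or 2 reads in wild type the ratio was 702 (194 to 5800) for AT3G43680, 759 (210 to 6270) for AT3G43681, 484 (86.3 to 19200) for AT1G33817, 432 (77.0 to 17100) for AT3G23725 and 230 (63.2 to 1900) for AT3G32240. Adjusted p of the genes named by fold or by p ranged from 2.05e-08 for AT1G31990 to 1.84e-05 for AT1G22010 (edgeR quasi-likelihood test, Benjamini-Hochberg). Multi-mapping reads were counted apart from genes, so reads that near-identical copies share would be missing from their counts. The values of the lipase pair and of the pseudogenes are uncertain for that reason. Those of antisense genes are uncertain because the counts ignore strand.

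The called genes were unevenly placed. Chromosomes 1 and 3 held 314 of them among 8497 tested genes (3.70%), against 115 among 9820 (1.17%) on chromosomes 2, 4 and 5, an odds ratio of 3.24 (95% interval 2.60 to 4.05, Fisher's exact test, two-sided, p = 7.38e-30, which treats genes as independent). This grouping of the chromosomes was chosen after the values were seen, and the p is not corrected for that choice. Of the 123 genes changed at least 16-fold, 100 were on chromosomes 1 and 3. In windows of 100 tested genes in locus order, a size chosen after the values were seen, the one from AT3G30718 to AT3G44100 held 39 called genes, 25 higher and 14 lower. The windows from AT1G34780 to AT1G43770 and from AT3G44110 to AT3G45870 held 22 and 20, and the one with PAPS1 held 5. PAPS1 lay inside a wider stretch of chromosome 1, from AT1G01010 to AT1G43770, whose windows held 1 to 22 called genes. From AT1G43775 onward they held 0 to 4. On chromosome 3 the windows from AT3G21030 to AT3G50260 held 4 to 39, and those outside that stretch 0 to 12. These stretches were chosen after the values were seen. By annotation, 321 of 17778 protein-coding genes were called, 141 higher and 180 lower, as were 103 of 358 pseudogenes, 70 higher and 33 lower. On chromosomes 2, 4 and 5 all 30 called pseudogenes were higher, while 35 of the 83 called protein-coding genes there were higher (Fisher's exact test, two-sided, p = 1.89e-09, also chosen after the values were seen).

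**Figure D2:**
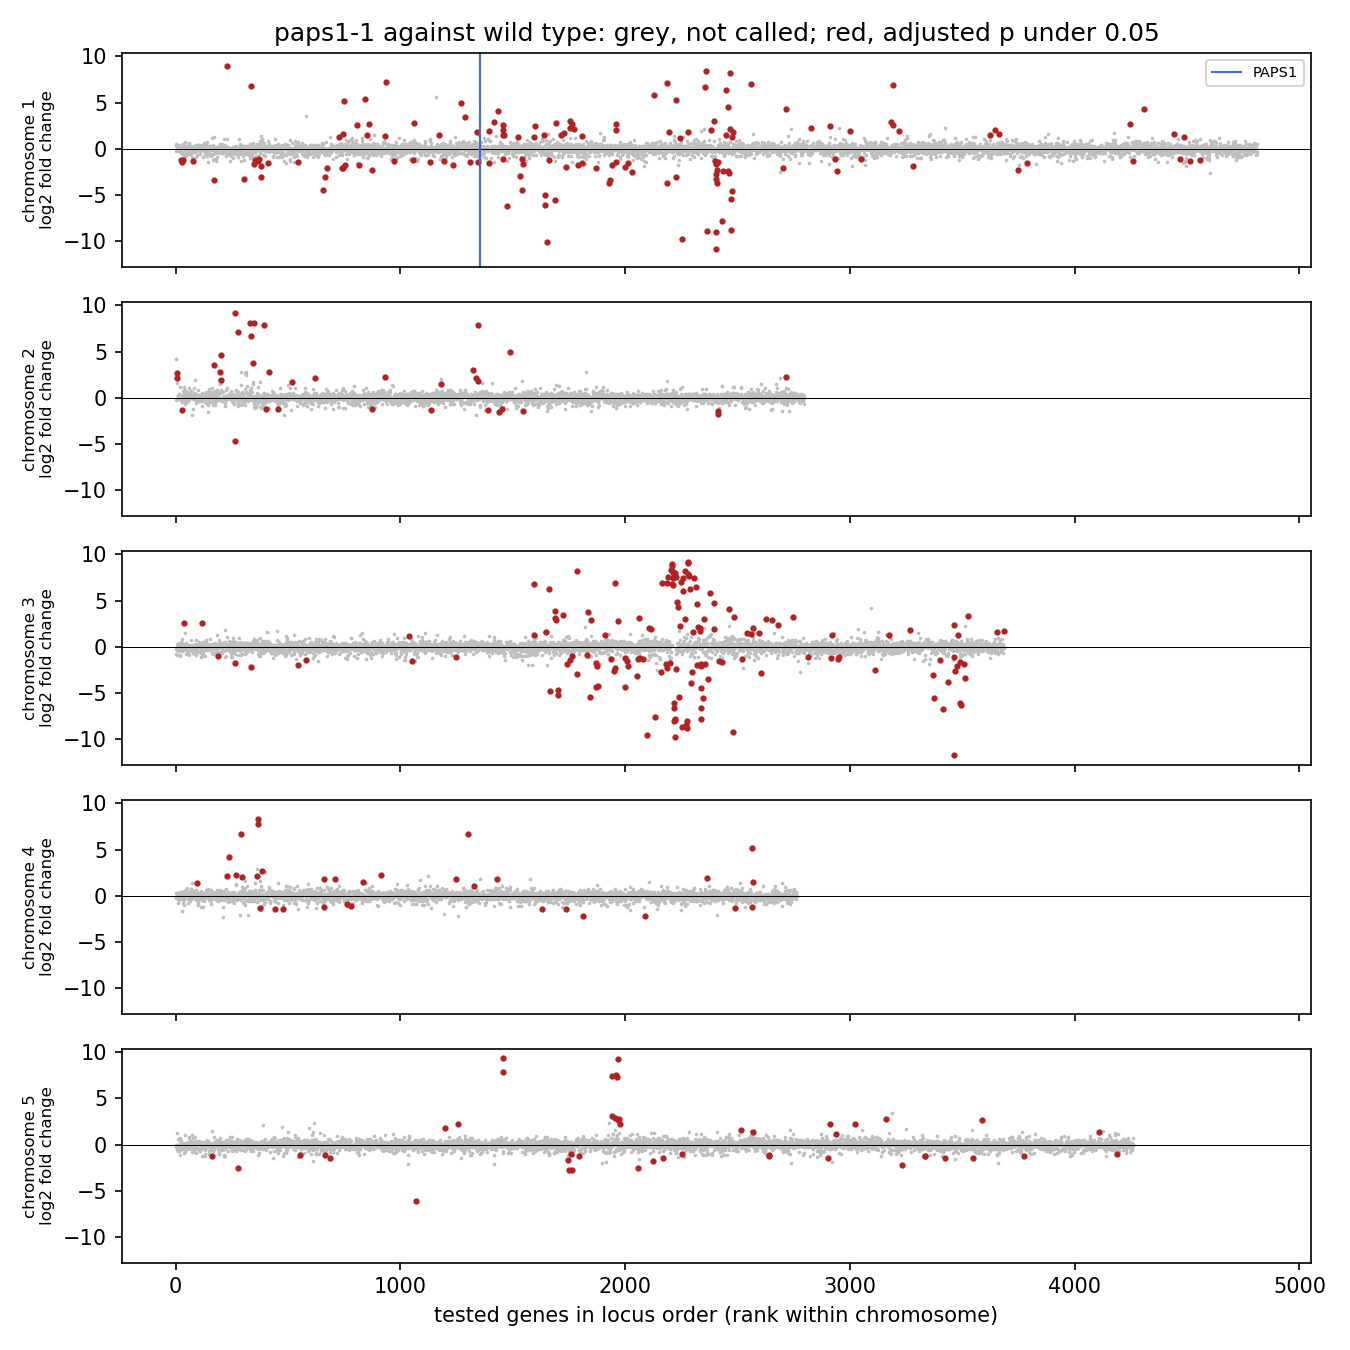
Each point is a tested gene, placed by its rank in locus order on chromosomes 1 to 5 (horizontal axis) and by its log2 fold change of paps1-1 against wild type (vertical axis); red points are the 429 called genes, grey points the rest, and the blue line marks PAPS1. The window from AT3G30718 to AT3G44100 holds 39 called genes. The window of PAPS1 holds 5 and lies in a stretch of chromosome 1 whose windows hold 1 to 22.

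The number of called genes depended on the filter, the libraries and the chromosomes tested. It was 1042 with no filter on low counts, 216 with a stricter filter, and 237 (145 higher, 92 lower, 220 of them among the 429) without wild-type replicate 3 and paps1-1 replicate 2. When chromosomes 2, 4 and 5 were tested alone it was 69 (48 higher, 21 lower), in place of 115 (66 higher, 49 lower) among the same genes. DESeq2 called 620, of which 237 were higher and 383 lower, in place of 213 and 216. With a covariate for the balance of the pollen and style lists in each library there were 179 higher and 108 lower. The genes called lower numbered 136 (217 higher) without wild-type replicate 3 and 131 (233 higher) without paps1-1 replicate 3.

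Markers of the cell types in the complex were compared next. All 12 tested genes of the sperm cell list had positive log2 fold changes, with a median of 0.71, and 2 of them rose. DAZ2, a zinc-finger regulator of sperm differentiation, rose from 1.83 ± 0.527 to 7.13 ± 0.986 CPM, and TET11, a tetraspanin gene, from 11.5 ± 3.26 to 44.9 ± 17.7 CPM (SD, n = 3; adjusted p = 0.00180 and 0.00184, edgeR quasi-likelihood test, Benjamini-Hochberg). TET11 (AT1G18520) lies in the window of 100 tested genes that holds PAPS1, so its rise cannot be told apart from an effect of its place. DAZ2 lies on chromosome 4. Adjusted over the list alone, 4 genes were higher. DMP9 and GCS1, which act in gamete fusion, had log2 fold changes of 0.96 (SE 0.29) and 0.75 (SE 0.26) and did not pass over all genes. In camera, a test of a list against all other genes, the sperm cell list was higher in paps1-1 (adjusted p = 1.60e-05 over 17 lists), with adjusted p = 0.707 with an estimated correlation between its genes. Its library means of log2 CPM were 3.36, 4.05 and 4.27 in wild type and 4.98, 4.77 and 4.32 in paps1-1 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow).

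The pollen and pollen tube list was lower in paps1-1 by camera (adjusted p = 2.43e-04, and adjusted p = 0.707 with an estimated correlation). Of its 56 tested genes, 50 had negative log2 fold changes, with a median of -0.39, but none passed over all genes or adjusted over the list alone by edgeR, while 10 had an unadjusted p under 0.05, 8 lower and 2 higher; DESeq2 called 2 lower and limma-voom 0. The 2 with positive log2 fold changes, named after their values were seen, were the NADPH oxidase gene RBOHJ (0.71, SE 0.30) and the profilin gene PRF5 (0.80, SE 0.37). ROPGEF8, an activator of the ROP GTPases of tip growth, stood at 165 ± 52.8 CPM in wild type and 81.1 ± 14.3 CPM in paps1-1 (SD, n = 3), the aquaporin TIP1;3 at 45.4 ± 10.2 and 20.02 ± 10.05 CPM, and MYB97, a regulator of pollen tube differentiation, at 316 ± 112 and 173 ± 16.7 CPM. The median log2 fold change of the list ranged from -0.574 to -0.113 with each library left out. Wild-type replicate 3 had the highest mean log2 CPM of this list, 9.44, against 8.86 and 8.47 in the other wild-type libraries and 8.65, 8.62 and 8.61 in paps1-1. Without it the camera adjusted p was 0.679 and the median -0.113. The sperm list kept its call without that library and without each other library in turn, with camera adjusted p up to 0.00443, and the range over all alternatives was 5.92e-08 to 0.707 for the sperm list and 1.03e-09 to 0.954 for the pollen list.

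The other tissue lists did not pass, and edgeR, DESeq2 and limma-voom called 0 of their genes, with 1 style and 1 photosynthesis gene at an unadjusted p under 0.05 by edgeR. The style, stigma and transmitting tract list (18 tested, 13 positive, median log2 fold change 0.21) had a camera adjusted p of 0.438. Within it NGA3, a style regulator, had a log2 fold change of 0.51 (SE 0.27), SPT, a carpel regulator, one of 0.41 (SE 0.25), and ETT, an auxin response factor, one of 1.26 (SE 0.56) at levels below 1 CPM. The ovule, synergid and egg cell list had 5 tested genes, among them STK (0.21, SE 0.26), ANT (-0.39, SE 0.31) and BEL1 (0.57, SE 0.32), and a camera adjusted p of 0.692. The tapetum and anther list had 2 tested genes, LAP6 (-0.36, SE 0.42) and EXL5 (-0.16, SE 0.32), and a camera adjusted p of 0.477. The locus measured under the symbol EXL5 (AT2G17230) is annotated as an EXORDIUM-like gene, not the tapetal lipase the list was meant to hold, so LAP6 was the only intended member measured in this test. The photosynthesis list had 14 of 18 positive genes and a camera adjusted p of 0.448. Its mean was highest in paps1-1 replicate 3, at 3.32 against 2.33 to 2.66 in the other 5 libraries, and RBCS1A, the small subunit of Rubisco, stood at 54.0 ± 10.98 CPM in wild type and 112 ± 124 CPM in paps1-1 (SD, n = 3). Its paps1-1 values were 39.0, 42.1 and 254 CPM, and without paps1-1 replicate 3 its log2 fold change went from 1.06 to -0.42. The difference of the pollen and style list means was 6.83 ± 0.65 in wild type and 6.37 ± 0.13 in paps1-1 (SD, n = 3; exact permutation test, two-sided, p = 0.3, smallest possible 0.1). Wild-type replicate 3 was the highest library, at 7.57. Without it the paps1-1 minus wild-type value went from -0.463 to -0.116, and with each library left out it ranged from -0.716 to -0.116.

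**Figure D3:**
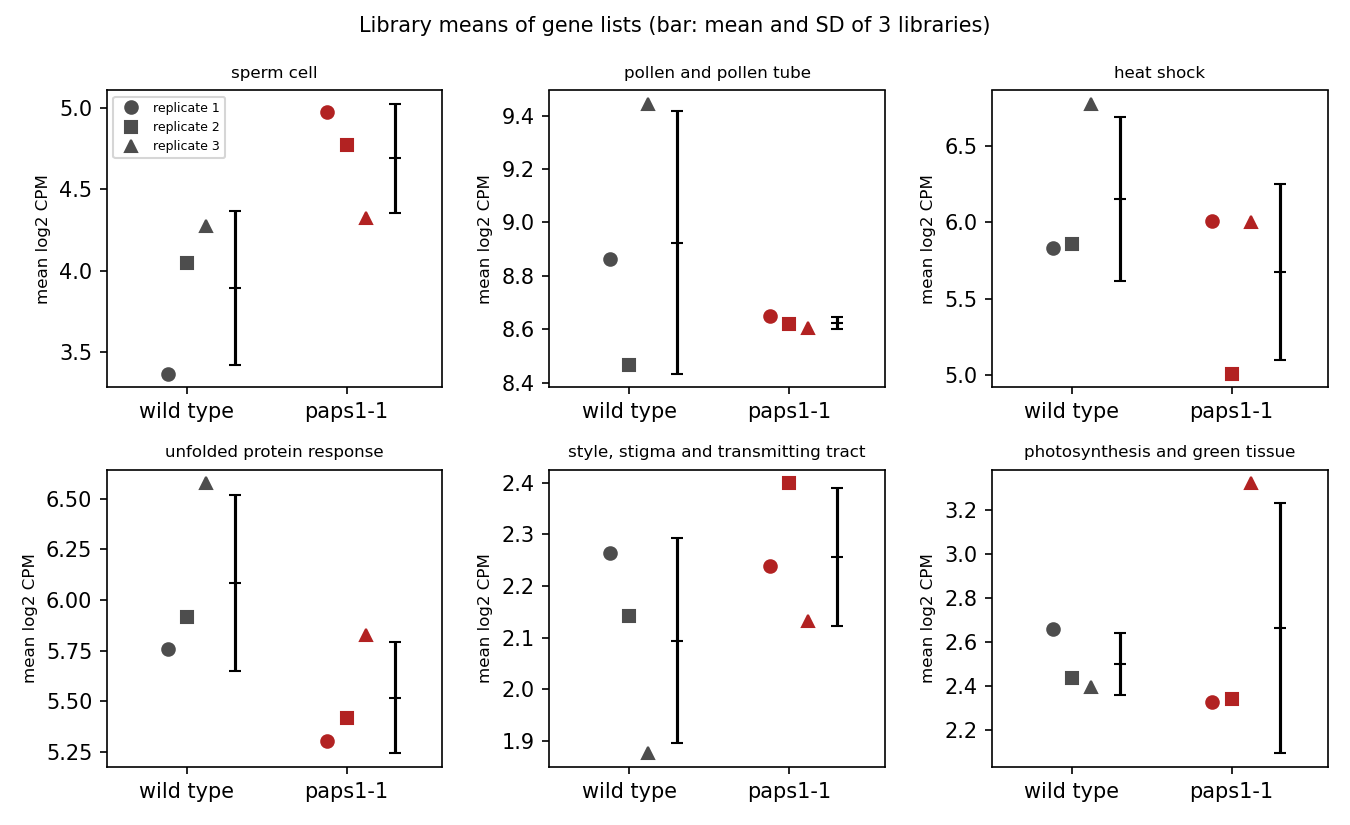
Mean log2 CPM of 6 gene lists in each library, with one marker per replicate and, beside them, the mean and SD of 3 libraries per genotype. The sperm cell means are 3.36, 4.05 and 4.27 in wild type and 4.98, 4.77 and 4.32 in paps1-1, and wild-type replicate 3 is the highest library for the pollen, heat shock and unfolded protein response lists.

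Of the genes in the unfolded protein response and heat shock lists, 1 passed over all genes. It was BIP3, an HSP70-type chaperone of the endoplasmic reticulum, which fell by 3.03 on the log2 scale (SE 0.63, adjusted p = 0.0145, edgeR quasi-likelihood test, Benjamini-Hochberg), from 30.0 ± 29.5 to 3.48 ± 1.00 CPM (SD, n = 3). BIP3 (AT1G09080) lies in the stretch of chromosome 1 around PAPS1 where called genes were concentrated. Its fall cannot be told apart from an effect of its place. Of 15 tested genes of the unfolded protein response list, 11 had negative log2 fold changes, 1 was lower over all genes and 6 were lower adjusted over the list alone; DESeq2 called 3 lower and limma-voom 0. The chaperones BIP2 (-1.07, SE 0.34) and CNX1 (-1.21, SE 0.35) and SDF2 (-0.85, SE 0.27) did not pass over all genes. Of 20 tested heat shock genes, 18 were negative, none passed over all genes or adjusted over the list alone by edgeR, and 3 had an unadjusted p under 0.05; DESeq2 called 1 lower and limma-voom 0. HOP3, a co-chaperone, had a log2 fold change of -1.36 (SE 0.38), ROF2 one of -1.19 (SE 0.44), BAG6 one of -1.18 (SE 0.53) and the transcription factor DREB2A one of -0.71 (SE 0.34). By camera both lists were called lower, with an adjusted p of 0.00159 for the unfolded protein response and 0.00170 for heat shock, and for each it was adjusted p = 0.707 with an estimated correlation.

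Both list calls were lost when single libraries were left out. Wild-type replicate 3 had the highest mean log2 CPM of both lists (6.57 for the unfolded protein response, 6.77 for heat shock), and paps1-1 replicate 2, the library with 4541233 gene reads, the lowest for heat shock (5.01). Without wild-type replicate 3 the camera adjusted p was 0.145 and 0.580, without paps1-1 replicate 2 it was 0.355 for heat shock. The log2 fold change of BIP3 was -1.94 without wild-type replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.122); without paps1-1 replicate 2 it was -2.90, about as large as with all libraries, and missed the threshold with fewer samples (adjusted p = 0.0591). Over all alternatives the range was 1.21e-04 to 0.707 for the unfolded protein response list, 1.21e-04 to 0.819 for heat shock and 8.44e-21 to 0.357 for BIP3.

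In the redox list, CAT3 (AT1G20620), a catalase, fell by 1.64 on the log2 scale (SE 0.36, adjusted p = 0.0190, edgeR quasi-likelihood test, Benjamini-Hochberg), from 24.9 ± 13.9 to 7.81 ± 2.40 CPM (SD, n = 3). It was the only one of 23 tested members that passed, over all genes and adjusted over the list alone; CAT2 (0.71, SE 0.35), TRX5 (-0.67, SE 0.29) and UPOX (0.65, SE 0.32) did not, and the list had a camera adjusted p of 0.680. CAT3 did not pass the edgeR test without wild-type replicate 3 (adjusted p = 0.0683), paps1-1 replicate 1 (0.0587) or paps1-1 replicate 2 (0.0840). Its log2 fold change was -1.115 without wild-type replicate 3 and -0.999 with the covariate for the balance of pollen and style lists (edgeR adjusted p = 0.111). Without paps1-1 replicate 1 or 2 it was -1.528 and -1.549, about as large as with all libraries, and missed the threshold with fewer samples. The adjusted p ranged from 7.13e-07 to 0.224 over all alternatives, DESeq2 and limma-voom among them. CAT3 also lies in the stretch of chromosome 1 around PAPS1, so its fall cannot be told apart from an effect of its place. All 19 tested genes of the salicylic acid and immune list were positive, with a median log2 fold change of 0.19, none passed over all genes or adjusted over the list alone by edgeR, 1 had an unadjusted p under 0.05, and the camera adjusted p was 0.0561. DESeq2 and limma-voom called 0 of them. The list was called higher by camera with limma-voom (adjusted p = 0.0298), with the stricter filter (0.0309), without wild-type replicate 1 (0.00654) and without paps1-1 replicate 2 (0.0474), within a range of 0.00654 to 0.819 over all alternatives. With all libraries it had adjusted p = 0.707 with an estimated correlation. PR5, a pathogenesis-related protein, had a log2 fold change of 0.65 (SE 0.28), WRKY70 one of 0.68 (SE 0.40) and WRKY40 one of 0.42 (SE 0.24). In the wounding and jasmonate list (18 tested, 13 positive, camera adjusted p = 0.383), LOX2, a lipoxygenase of jasmonate synthesis, stood at 8.12 ± 0.858 CPM in wild type and 17.1 ± 4.65 CPM in paps1-1 (edgeR adjusted p = 0.0509 over all genes; 1 gene passed adjusted over the list alone, DESeq2 called 1 gene of the list higher and limma-voom 0), AOC1 had a log2 fold change of 0.84 (SE 0.32) and VSP1 one of -0.58 (SE 0.28). LOX2 and AOC1 lie in the stretch of chromosome 3 where called genes were concentrated, LOX2 in a window with 20 of them. On chromosomes 2, 4 and 5 alone the list median went from 0.103 to -0.037. A rise of LOX2 and AOC1 cannot be told apart from an effect of their place.

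Of the lists of RNA processing and silencing, only that of RNA-directed DNA methylation held a gene called by edgeR. IDN2, an RNA-binding component of that pathway, rose by 1.45 on the log2 scale (SE 0.26, adjusted p = 0.00387, edgeR quasi-likelihood test, Benjamini-Hochberg), from 5.96 ± 1.17 to 16.2 ± 1.56 CPM (SD, n = 3). It was also the 1 gene of the 29 that passed adjusted over the list alone. The dicer gene DCL3, the DNA demethylase gene ROS1 and the DNA methyltransferase gene CMT2 had log2 fold changes of 1.1 (SE 0.33), 0.70 (SE 0.29) and 0.74 (SE 0.35) and did not pass. That list was not called by camera (adjusted p = 0.477), while fry's test for change in either direction passed (adjusted p = 0.0388). IDN2 and DCL3 lie on chromosome 3, where called genes were concentrated, and DCL3 lies in the window with 39 of them. On chromosomes 2, 4 and 5 alone the list median went from 0.035 to -0.088. A change of the pathway therefore cannot be told apart from the place of these genes.

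The machinery of polyadenylation itself held no gene called by edgeR. None of 25 tested genes of 3' end processing passed over all genes or adjusted over the list alone by edgeR, with 0 at an unadjusted p under 0.05 and a camera adjusted p of 0.477; CFIS2, a cleavage factor subunit, had a log2 fold change of -0.48 (SE 0.28). None of 18 genes of poly(A) binding, deadenylation and decapping passed, with 1 at an unadjusted p under 0.05 and a camera adjusted p of 0.909; DESeq2 called 1 of them lower. PAB5, a poly(A)-binding protein of reproductive tissue, stood at 473 ± 114 CPM in wild type and 249 ± 59.2 CPM in paps1-1, PAB6 at 147 ± 29.4 and 202 ± 27.6 CPM (SD, n = 3), and the deadenylase gene CAF1a had a log2 fold change of 0.42 (SE 0.24). None of 12 genes of the nuclear exosome and RNA surveillance passed, with 0 at an unadjusted p under 0.05 and a camera adjusted p of 0.909; the helicase gene MTR4 had a log2 fold change of 0.35 (SE 0.22) and UPF1, a factor of nonsense-mediated decay, one of -0.42 (SE 0.24). In every other case DESeq2 and limma-voom called 0 genes of these lists.

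Auxin-related lists did not pass with all libraries. Only 2 of 15 SAUR genes, SAUR66 (-0.45, SE 0.44) and SAUR67 (-0.91, SE 0.58), had enough reads to be tested, and the camera adjusted p was 0.438. In the auxin response list, HAT2 had a log2 fold change of -0.60 (SE 0.26), IAA14 one of -0.75 (SE 0.39), IAA19 one of -0.49 (SE 0.41) and DFL1 one of 0.32 (SE 0.29). Its 13 tested genes had a median log2 fold change of 0.10 but a mean of -0.04 and a camera test in the downward direction (adjusted p = 0.909), so these differed in sign. No gene of either list passed over all genes or adjusted over the list alone by edgeR, and 1 auxin response gene had an unadjusted p under 0.05; DESeq2 and limma-voom called 0. Without wild-type replicate 3 and paps1-1 replicate 2 camera called both lists lower (auxin response median -0.61, adjusted p = 0.00557; SAUR median -1.49, adjusted p = 0.00573), and without paps1-1 replicate 2 alone it called the SAUR list lower (median -0.86, adjusted p = 0.0474). These calls use the preset correlation; with all libraries the lists had adjusted p = 0.948 (auxin response) and adjusted p = 0.707 (SAUR) with an estimated correlation. Over all alternatives the camera and fry adjusted p ranged from 0.00557 to 0.995 for auxin response and from 0.00573 to 0.835 for SAUR.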

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

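No test chosen after the results were seen is reported in this part, and no explanation was tested for these values. They were picked out because reads outside the gene counts exceeded the level of every wild-type library. Multi-mapping reads made up 28.0% of all reads in paps1-1 replicate 1 and 74.6% in paps1-1 replicate 2, against 7.28%, 11.9% and 15.1% in wild type; paps1-1 replicate 3 had 7.75%. Reads outside annotated genes made up 4.95% in paps1-1 replicate 1 and 9.93% in paps1-1 replicate 2, against 2.76%, 3.53% and 3.95% in wild type and 2.71% in paps1-1 replicate 3. In the same 2 libraries the 18S ribosomal RNA gene AT3G41768 took 0.732% and 10.5% of gene reads, against 0.110%, 0.140% and 0.265% in wild type.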

How the results depend on the processing

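Leaving out ribosomal RNA genes, testing chromosomes 2, 4 and 5 alone, leaving out wild-type replicate 3 with paps1-1 replicate 2, testing protein-coding genes alone and matching by identifier were tests chosen after the results were seen. The 429 called genes became 1042 with no filter, 864 of them among the 18317 genes, as the prior degrees of freedom of the test went from 11.2 to infinite and each gene's own spread no longer entered. They became 216 with the stricter filter, under which 240 of the 429 were tested. On chromosomes 2, 4 and 5 alone they became 69, against 115 called among the same 9820 genes when all chromosomes were tested together. With wild-type replicate 3 and paps1-1 replicate 2 both left out, and so with fewer samples, they became 237. With each library left out, and so with fewer samples, the number lay between 333 and 456, and between 302 and 358 of the 429 were among them. The other alternatives gave between 287 (composition covariate; 179 higher, 108 lower) and 620 (DESeq2). The 4 called lists became 1 with the composition covariate, which is built from the pollen list itself, 0 with an estimated correlation and 0 by fry; with each library left out there were 1 to 5, the 1 being the sperm list without wild-type replicate 3. PAPS1 kept its negative sign and did not pass under any of its alternatives. The 44 called genes named in the text were chosen for a large fold change or a small p, so they do not stand for all 429. Of these 44, 40 were called with each library left out. AT5G55980 was not without paps1-1 replicate 2 or 3, though its log2 fold change of -1.234 and -1.155 stayed near the -1.24 of all libraries. MIR156c was not without wild-type replicate 3, where its log2 fold change went from -2.20 to -1.632. No scaling moved the median log2 fold change of all genes by 0.1 or more.

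Replicate numbers did not pair the libraries: deviations from the group means correlated at -0.256, 0.126 and -0.151 across genes for numbers 1 to 3, and not every library correlated best with its own number. With the replicate block 482 genes were called, 403 of them among the 429, and 4 lists. No organelle genes were analysed here, so leaving them out was not run.

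Some medians or log2 fold changes that had not passed, and a few list medians, changed direction; the cause was not tested. For lists the direction is that of the camera test. The auxin response median was -0.027 with stranded counts, 0.173 with the stricter filter and 0.144 with the replicate block. With the composition covariate the exosome median was -0.074, the pollen median 0.013, the style median 0.024, PAB3 0.057, PAPS2 0.290 and PAPS4 0.014. On chromosomes 2, 4 and 5 alone the exosome median was 0, poly(A) binding -0.095, RNA-directed DNA methylation -0.088 and wounding -0.037. Without both of those libraries heat shock was 0.193, the exosome -0.095, ovule -0.076, style -0.137, PAB3 0.027, PAPS2 0.224 and STK -0.076. With the stricter filter the ovule median was -0.071. With each library left out the ranges were -0.340 to 0.272 (auxin response), -0.078 to 0.158 (exosome), -0.248 to 0.450 (photosynthesis), -0.023 to 0.123 (poly(A) binding), -0.031 to 0.307 (redox), -0.860 to -0.102 (SAUR), -0.887 to 0.407 (BAN), -0.417 to 1.466 (RBCS1A), -0.399 to 0.207 (EXL5) and -0.580 to 0.159 (PAPS2). Depth limits paps1-1 replicate 2 most, where 3 reads correspond to 0.638 CPM.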

Other observations

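Tests chosen only after the result was seen were those of chromosomes 1 and 3 against 2, 4 and 5, of adjacent called genes, of called pseudogenes against protein-coding genes, of the sperm list against the pollen tube list, and of the pseudogenes in paps1-1 replicate 3. Away from chromosomes 1 and 3, named after their values were seen, PUM16, a Pumilio-type RNA-binding protein gene, rose from 1.47 ± 0.475 to 9.75 ± 3.19 CPM (SD, n = 3; log2 fold change 2.71, SE 0.35). The lectin-family gene AT5G49850 rose by 2.19 (SE 0.29) and AT2G18340, which encodes a late embryogenesis abundant domain, by 2.09 (SE 0.31) on the log2 scale. The pseudogenes AT2G04135, AT2G28980, AT2G01034 and AT5G34851 rose by 4.65, 2.14, 2.74 and 2.73, and the non-coding RNA AT4G12917 by 1.76. RBK1, a kinase that binds ROP GTPases, fell from 77.0 ± 9.66 to 28.5 ± 7.57 CPM, and AT4G28290 from 116 ± 17.5 to 24.8 ± 8.97 CPM. The leucine-rich repeat gene AT5G25550, AT2G43220, AT5G54560 and AT5G38400 fell by 2.78, 1.72, 2.22 and 1.80 on the log2 scale, AT5G55980 by 1.24, and MIR156c, the precursor of a microRNA that targets SPL transcription factors, by 2.2. The adjusted p of these genes ran from 4.08e-05 for AT2G04135 to 0.00919 for MIR156c (edgeR quasi-likelihood test, Benjamini-Hochberg).

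Among 20 gene families taken from product names, camera called NBS-LRR disease resistance genes higher (72 tested, adjusted p = 4.41e-05, 4 called higher and 2 lower, all 6 on chromosomes 1 and 3) and pentatricopeptide repeat genes higher (213 tested, adjusted p = 0.00800). None of the pentatricopeptide repeat genes was called by edgeR, DESeq2 or limma-voom; at an unadjusted p under 0.05 by edgeR there were 14 higher and 2 lower. It called lower the S1 self-incompatibility family (26 tested, adjusted p = 9.93e-05, 2 called higher and 3 lower) and pectin methylesterase inhibitors (53 tested, adjusted p = 7.13e-04). Of these inhibitors edgeR called 0, with 8 lower at an unadjusted p under 0.05, DESeq2 called 2 lower and limma-voom 0. With an estimated correlation the smallest adjusted p over the families was 0.534. That value had been set beforehand as counting against a shared family difference, but a missed threshold with 3 libraries per genotype does not exclude one, so the question stays open.

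The concentration of called genes on chromosomes 1 and 3 had an odds ratio of 3.24 (95% interval 2.60 to 4.05). Without paps1-1 replicate 2, the shallow library rich in ribosomal RNA, it was 4.05 (3.12 to 5.32), so that library was not its cause. Chromosome segments in the mutant line that differ from the reference may contribute: on chromosomes 1 and 3, 54 called genes were followed by another called gene, against a median of 12 and a maximum of 27 in 10000 shuffles (permutation p = 1e-04, the smallest possible). The comparison chromosomes also exceeded their shuffles (8 against a maximum of 7), and pseudogenes gather around centromeres, so segments and a regional response cannot be told apart here. Pseudogenes alone do not account for the concentration, which protein-coding genes also showed. On chromosomes 1 and 3, 238 of 8249 protein-coding genes (2.89%) were called, against 83 of 9529 (0.871%) on chromosomes 2, 4 and 5. A response to the mutation itself stays open and untested.

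Without wild-type replicate 3 the camera adjusted p was 0.679 for the pollen tube list and 0.145 for the unfolded protein response list. Neither call was lost when another single library was left out. For the pollen tube list the median was -0.113 without it, which an effect of that library alone would give. For the unfolded protein response the median went from -0.499 with all libraries to -0.15 without wild-type replicate 3. An effect of that library alone would give this shrinkage as well. The missed threshold itself came with fewer samples and does not show that one library made the call. The 4 genes named from that list were lower in every paps1-1 library than in every wild-type library. They were picked for the smallest p in these same data, so this does not count against an effect of wild-type replicate 3. For heat shock the adjusted p was 0.580 without wild-type replicate 3 but also 0.355 without paps1-1 replicate 2, so one library alone cannot be told apart from both. Over all alternatives the adjusted p ranged up to 0.954, 0.707 and 0.819. Less pollen tube RNA in the mutant complexes would lower the sperm cell list as well, because sperm cells travel in the tube. The median log2 fold change of the sperm list lay 1.1 above that of the pollen tube list (bootstrap interval over genes 0.765 to 1.438, which treats genes as independent), and both medians were known before the comparison was chosen. In single libraries the sperm minus the pollen tube list mean of log2 CPM was -5.50, -4.42 and -5.17 in wild type and -3.67, -3.85 and -4.28 in paps1-1 (exact permutation test, two-sided, p = 0.1, the smallest possible). The libraries are too few to exclude less pollen tube RNA, and a difference within the tube between genotypes stays open and untested.

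The 30 pseudogenes called on chromosomes 2, 4 and 5, all higher in paps1-1, had median CPM of 0 in every wild-type library and of 3.71, 2.98 and 2.40 in paps1-1 replicates 1 to 3; 16 had no read in wild type. Stray DNA or ribosomal RNA in the mutant libraries may contribute, yet replicate 3, at 2.40, had a multi-mapping share within the wild-type range and an outside-gene share below it. That value decides nothing, as these genes were picked for being higher in paps1-1 and it comes from 1 library. Over all 190 tested pseudogenes of these chromosomes, 129 had positive log2 fold changes (median 0.28; camera p = 0.119 with an estimated correlation). A p of 0.05 or more had been set beforehand as counting against a general rise, but with 3 libraries per genotype a missed threshold does not exclude one, so stray DNA and a general rise cannot be told apart here.

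Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, gave 429 genes called by edgeR, and the highest other gave 0. For lists, 7 of the 10 splits, the real one among them, called at least 4, and the highest other called 6. Groupings that mix the genotypes thus called as many lists, so the number of called lists does not set the genotypes apart. For genes, the 10 splits are too few for a share under 0.05.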
